A study of Mus musculus with 12 samples.

How the data were processed

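RNA of mouse oocytes was measured at 3 stages named NGO, GO and FGO, in a control (WT in the labels, headed Rnaseh1 fl/fl in the table) and in the oocyte deletion of Rnaseh1 (KO in the labels, headed oo-/-). The labels list 12 samples, 2 per genotype and stage, each of 10 oocytes with 100 pg of ERCC spike-in RNA added. Libraries were made with Smart-seq2 from polyadenylated RNA and 500 pg of cDNA and read as unstranded 150 bp pairs on an Illumina HiSeq X instrument, per the labels. Per the submitters' processing notes, reads were processed with Trim Galore 0.6.7, HISAT2 2.2.1 and Cufflinks 2.2.1 on mm10. The values are FPKM that the authors adjusted to the spike-in, as the deposited file is named. The adjustment formula and the gene annotation are not given in the sources used here.

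The table held 25912 lines for 25164 symbols and 6 value columns, 1 for each genotype and stage. It does not say whether a column is a mean of the 2 samples, a pool or 1 of them. Lines with 2 spreadsheet error marks (Gm5901 and Syn3) were left out. For the 333 symbols on more than 1 line, the line with the largest mean was kept, which left 25162 genes. Of these, 10110 had a mean of at least 1 FPKM over the columns and were compared, 44 of them with a symbol on more than 1 line and 89 listed at 0 in some column. The table held 0 spike-in lines and 0 mitochondrially encoded genes, so the lists of mitochondrially encoded proteins and ribosomal RNA were not analysed here. Read depth per sample is unknown, so the counting error of a value is unknown too.

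The comparisons, gene lists and naming rule were written before the data were examined, for 2 samples per group with moderated linear models, camera gene-set tests and exact permutation tests. With a single column per group none of these could be run, nor could the replicate block, fits within a group, the intensity trend or leaving out a sample. Differences were instead computed on log2(FPKM + 1) and called at 2-fold or more, a difference of at least 1. Comparisons were KO against WT at each stage and averaged over stages, each stage step within WT and within KO, and the change of the KO to WT difference between stages. Each was made with values as deposited and again after every column was divided by its median ratio to the geometric mean column. These factors were 0.514, 1.29 and 1.31 for WT and 0.453, 1.22 and 2.26 for KO at NGO, GO and FGO.

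For each of the fixed gene lists with at least 5 members compared, the rescaled median difference was placed among 10000 random lists of the same size, drawn from 20 bins of mean expression. The percentile describes the list and is no p-value, since genes vary together. Lists of theca and stroma, immune and endothelial and blood markers had fewer members compared and are given as FPKM values. The oxidative phosphorylation, ribosomal protein, RNA polymerase II and double-strand break repair lists were placed again among random lists matched on expression and transcript length or GC content, in 10 bins each. The first 2 of these were also placed, by a choice made after the data were seen, among random lists of the 50 genes nearest in length to each member, with both lists kept in the pool or left out. Lengths and GC came from GENCODE M21 (99.4% of genes compared) and coordinates from RefSeq on GRCm38.p6 (99.9%). Steps in WT and KO were compared across genes with Pearson r, Spearman rho and an orthogonal regression, whose error came from 200 resamplings of genes.

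The naming rule was adapted because no p-value exists. It names Rnaseh1, then per stage the 10 genes with the largest higher and lower values in KO, with at least 5 FPKM in the higher column and a proper gene name. It names 5 per direction for each WT step, 10 per direction for the average among genes of the same rescaled direction at each stage, and the 5 largest shifts between stages. For each list and comparison it names up to 4 members by the size of the rescaled difference. Transcripts of named genes were searched against GENCODE M21 with blastn 2.17.0, at 95% identity or more over at least 50% of the longest transcript, and gene overlaps were taken from RefSeq.

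Alternatives were a pseudocount of 0.1, no filter, a mean of at least 5, equal column totals and the median-ratio scaling. Chosen after the data were seen were, besides the match on nearest length, 2 more, namely only symbols on 1 line and no genes listed at 0. The steps were tested on simulated data with 10110 genes per stage. Of genes made 4-fold higher, 88%, 95% and 95% were called at NGO, GO and FGO, and of genes made 4-fold lower 66%, 86% and 86%. Of unchanged genes, 0.0303%, 1.38% and 1.53% were called. A true slope of 0.8 was found as 0.800. The simulated noise had a set size, equal for all genes of a stage and equal in both steps of the slope test. The error of the real values is unknown, so these shares check the steps only and give no rate of false calls in these data. Software was Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.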

Results

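The series measured polyadenylated RNA in mouse oocytes with Rnaseh1 floxed or deleted, at 3 stages of oocyte growth. Rnaseh1 encodes RNase H1, a nuclease that degrades the RNA strand of RNA-DNA hybrids such as those in R-loops. The labels name 12 samples of 10 oocytes each, 2 for each genotype (WT and KO) and stage (NGO, GO and FGO). The labels do not spell out the stage names. In this field they commonly stand for non-growing, growing and fully grown oocytes, and fully grown oocytes are known to become transcriptionally silent as they mature. The values used here came in 6 columns, 1 per genotype and stage, headed fl/fl (the floxed control, called WT here as in the labels) and oo-/- (the oocyte deletion, called KO), as FPKM adjusted to a spike-in by the authors. No difference below therefore has a replicate check, and no p-value, SD or n is given. Genes are called higher or lower when the KO and WT columns differed at least 2-fold on the log2(FPKM + 1) scale, that is by 1 or more. The number of reads behind each column is unknown. Comparisons cover the 10110 genes with a mean of at least 1 FPKM over the columns. "After rescaling" means that each column was first divided by its median ratio to the other columns, which sets the median KO to WT difference close to 0.

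Rnaseh1 itself lies on chromosome 12 from position 28649601 to 28659592 in mm10. In the WT columns it was listed at 8.61 FPKM in NGO, 27.8 in GO and 29.1 in FGO. The KO columns held 0.931, 3.10 and 8.02 FPKM at the same stages. KO was thus at 10.8% of WT in NGO, 11.2% in GO and 27.6% in FGO. After rescaling, the shares were 12.3%, 11.8% and 16.0%. Which part of the gene is removed in KO is not given in the sources used here.

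The first question is how the summed FPKM compared between genotypes at each stage. How far a sum stands for the RNA of an oocyte cannot be told. The adjustment formula is not given, and only polyadenylated RNA was measured. A common factor on the KO FGO column would raise its sum. The FPKM of all genes summed to 156837 in WT and 132093 in KO at NGO, a KO to WT ratio of 0.842. At GO the sums were 384421 in WT and 355744 in KO, a ratio of 0.925. At FGO they were 460906 in WT and 729690 in KO, a ratio of 1.58. The WT sum at FGO was 1.20 times that at GO, and the KO sum was 2.05 times its GO value. Genes at 1 FPKM or more numbered 8314 in WT and 8168 in KO at NGO. They numbered 10082 and 9931 at GO. At FGO the numbers were 9819 in WT and 11082 in KO, 1263 more in KO. The cutoff was applied to values as deposited, so a common factor on the KO FGO column would raise this number too. The KO to WT ratio of gene numbers at FGO was 1.13 at this cutoff, 1.08 at 0.1 FPKM and 1.22 at 5 FPKM. Without the 10 genes of largest mean the ratio of sums at FGO was 1.58.

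**Figure D1:**
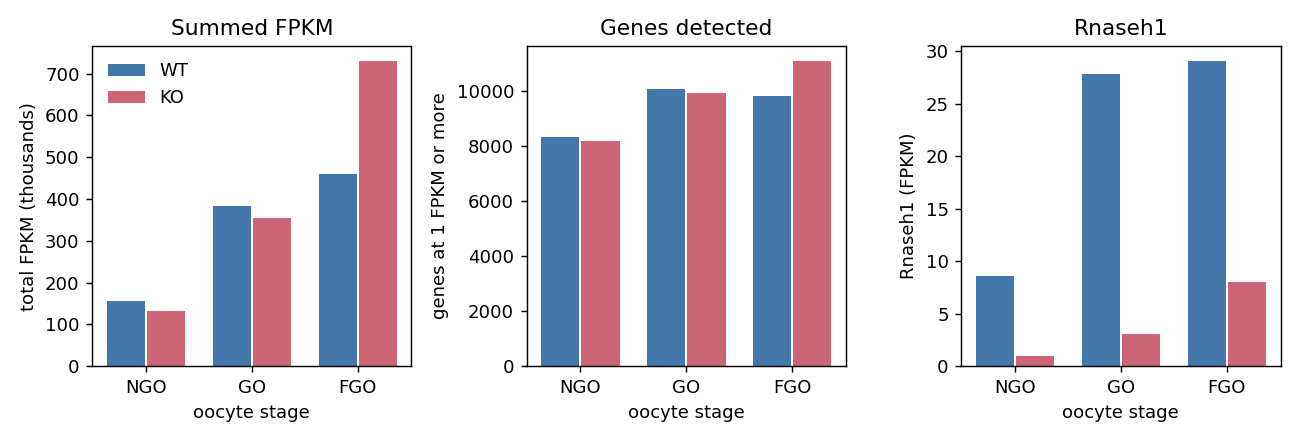
Summed FPKM, number of genes at 1 FPKM or more, and Rnaseh1 FPKM for the WT (blue) and KO (red) column of each stage, 1 bar per column and no error bars because each group has a single column. The KO sum is below WT at NGO and GO and reaches 729690 against 460906 at FGO, while Rnaseh1 is lower in KO at each stage.

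At NGO Rnaset2a, a lysosomal ribonuclease, was listed at 13.0 FPKM in WT and 2.10 in KO. Ndufs5-ps, a pseudogene of a complex I subunit, was at 9.10 and 0.265. Ppp1r35 (6.25 and 1.39), Tmem243 (12.1 and 3.79) and Trir (7.77 and 2.44) were also lower in KO. Also lower was Tcstv1, a gene of the two-cell embryo, at 8.95 FPKM in WT and 2.38 in KO. Dppa2, a chromatin factor of pluripotent cells, was at 17.2 and 5.55. Sap30, a subunit of the Sin3 histone deacetylase complex, was at 12.3 and 4.28. Nlrp9b, an oocyte NLR-family gene, was at 24.4 and 10.1.

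Among the 10 largest higher values in the KO NGO column, Oog1, an oocyte-expressed gene, stood at 9.54 FPKM against 0.0670 in WT. Phgdh, the first enzyme of serine synthesis, stood at 6.35 against 2.503. The other 8 stayed under 2-fold on this scale as deposited. They were Stk36 (log2 difference 0.81, and 1.01 after rescaling), Id1 (0.70), Llgl1 (0.66), Snx5 (0.63), Marcksl1 (0.62), Rpl39 (0.62), Hdac6 (0.59) and Pwwp3a (0.54). In all, 3 genes were higher and 33 lower in KO. After rescaling the split was 13 higher and 36 lower, and with equal column totals 25 and 39. With a pseudocount of 0.1 it was 48 and 224. The median log2 difference was -0.11.

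Of the gene lists at NGO, the 41 measured genes of DNA double-strand break repair had a median of 0.01 as deposited and 0.16 after rescaling. The rescaled median lay at percentile 99.99 among 10000 random lists of like expression. Rad50 (12.5 FPKM in WT, 15.4 in KO) was above the median gene, and Rpa3 (25.9 and 13.5) and Lig4 (5.31 and 3.17) were below it. None of the 41 differed 2-fold, so that 0 were called. The 29 meiotic prophase genes had a rescaled median of 0.13 (percentile 98.45) and -0.01 as deposited, with Sycp3 at 30.03 FPKM in WT and 42.3 in KO, Mael at 19.2 and 27.2, and Hormad2 at 1.95 and 3.47. The 14 canonical histone genes had a rescaled median of -0.28, below all 10000 random lists, which were not matched on transcript length. H2ac1 was at 3.29 and 1.08 FPKM and H1f1 at 2.86 and 0.971. The 79 cytosolic ribosomal protein genes had a rescaled median of -0.17 (percentile 0.01), with 55 below the median gene. The 75 nuclear-encoded oxidative phosphorylation genes had -0.11 (percentile 2.13). Against lists matched on transcript length as well, the ribosomal and oxidative phosphorylation medians lay at percentiles 72.5 and 98.3 in bins. Among the 50 genes nearest in length they lay at 52.5 and 76.4.

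At GO the differences were wider and went both ways. Kdm1b, the H3K4 demethylase needed for maternal imprints, was at 31.6 FPKM in WT and 84.6 in KO. Nlrp5, a component of the subcortical maternal complex, was at 518 and 1274. Ect2, which activates RhoA in cytokinesis, was at 11.2 and 33.3. Llgl1, a cell polarity gene, was at 7.34 and 24.3. Mdm2, the ubiquitin ligase of p53, was at 31.3 and 73.7. As deposited, Padi6, also of the maternal complex (3216 and 5524 FPKM, log2 difference 0.78), and Plk1, a mitotic and meiotic kinase (41.5 and 83.7, 0.996), stayed under 2-fold. After rescaling Plk1 passed it, at 1.07.

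The 10 largest higher values in the KO GO column further held Ddi2 (6.40 FPKM in WT and 29.7 in KO), S100a16 (1.19 and 7.65), Ifitm10 (1.41 and 7.57), Zfp97 (3.38 and 11.3), Wdr19 (1.23 and 5.01) and Fbxw5 (3.77 and 11.8). Rn45s, the ribosomal RNA precursor, was listed at 0 in WT and 3173 in KO, and Tgoln2 at 8.39e-07 and 5.18. An entry at or near 0 can be a failed estimate, so no fold is given for these.

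The 10 largest lower values in the KO GO column included Zbtb18, a transcriptional repressor, at 41.5 FPKM in WT and 12.7 in KO. Lsm5, part of the ring that binds U6 RNA, was at 173 and 51.1. Clec2f was at 12.8 and 1.97, Rhox8 at 5.15 and 0.703, and Tmem267 at 14.6 and 4.16. The small membrane protein genes Smim27 (6.41 and 0.890) and Smim26 (5.96 and 1.11) were also lower. Amd1, an enzyme of polyamine synthesis, was at 8.65 and 0.01501, and Ndufs5-ps at 13.8 and 0.258. In all, 96 genes were higher and 205 lower in KO. After rescaling the split was 106 higher and 129 lower, and with equal column totals it turned to 156 higher and 134 lower. With a pseudocount of 0.1 in place of 1 the number of 2-fold genes was 670 in place of 301. The median log2 difference was -0.09.

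The oxidative phosphorylation and ribosomal protein genes were lower as groups at GO. Of the 75 oxidative phosphorylation genes, 61 lay below the median gene, 5 were at least 2-fold lower and 0 higher. Their median log2 difference was -0.50 as deposited and -0.42 after rescaling, below all 10000 random lists. Cox7c was at 36.3 FPKM in WT and 14.3 in KO, Uqcrh at 23.7 and 10.3, Ndufc1 at 42.7 and 19.3, and Cox6b1 at 8.95 and 2.47. Of the 79 ribosomal protein genes, 72 lay below the median gene and 6 were at least 2-fold lower. Their median was -0.47 as deposited and -0.39 after rescaling, below all 10000 random lists. Rpl41 was at 102 and 41.0 FPKM and Rps28 at 5.71 and 1.40. Against lists matched on transcript length as well, the medians lay at percentiles 0.43 for oxidative phosphorylation and 4.29 for ribosomal proteins. All 632 genes with transcripts of up to 1000 nt had a rescaled median of -0.40 at GO and -0.37 at FGO, and these include members of both lists.

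Other lists at GO stood above the median gene. The double-strand break repair list had a rescaled median of 0.20 (percentile 99.56), with Xrcc3 at 17.7 FPKM in WT and 32.3 in KO and Rad51b at 1.97 and 3.68. Lig4 (35.9 and 17.2) and Rpa3 (79.3 and 39.7) went the other way. The 44 genes of meiotic maturation had 0.15 (percentile 98.59), with Map2k1 at 27.2 and 52.5 and Ppp2r1a at 54.6 and 104 FPKM. Cdc25a, an activator of cyclin-dependent kinases, was at 37.2 and 17.4. The meiotic prophase list had 0.18 (percentile 98.16), with Smc1b at 5.47 and 13.5 and Tex15 at 1.94 and 4.90. The 42 genes of RNase H and R-loop resolution, Rnaseh1 among them, had 0.15 (percentile 97.95, not matched on transcript length). At the other stages this list had 0.06 (NGO, percentile 85.7) and -0.01 (FGO, percentile 35.5). Among its members at GO, Top3b, a topoisomerase that also acts on RNA, was at 9.98 and 24.8 FPKM. Thoc5 was at 5.38 and 10.1 and Ddx41 at 19.4 and 33.2. Counts of 2-fold calls in these 4 lists did not exceed 2 in either direction.

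At FGO most genes were higher in KO as deposited. Of the 10110 genes, 9649 had a higher value in KO, 2612 were at least 2-fold higher and 16 at least 2-fold lower. The median log2 difference was 0.72, a fold of 1.65. After rescaling, 170 genes were higher and 95 lower. The direction of a gene near the median at FGO thus depends on whether the authors' spike-in scale is kept.

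**Figure D2:**
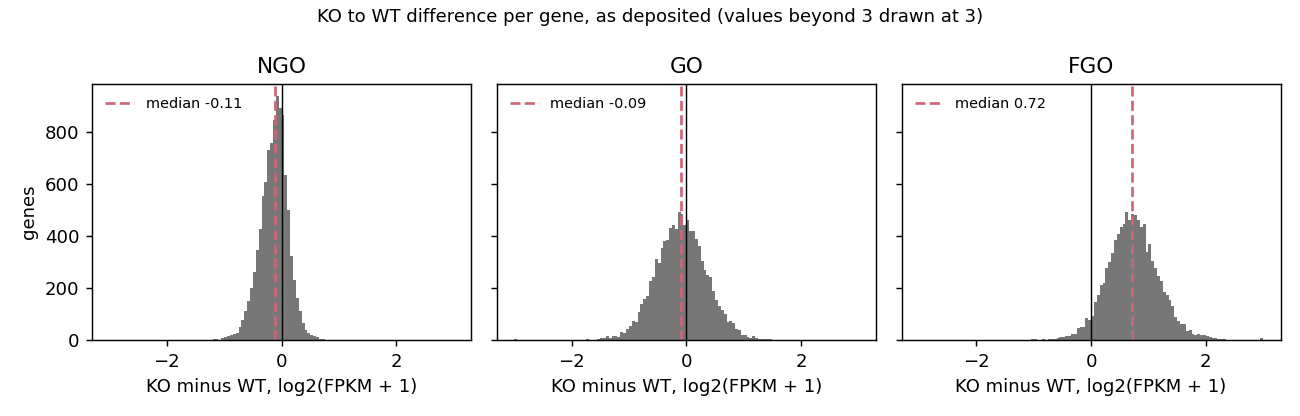
Histograms of the KO minus WT difference in log2(FPKM + 1) per gene, as deposited, for NGO, GO and FGO, with a dashed line at the median. The medians are -0.11, -0.09 and 0.72.

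Among the 10 largest higher values in the KO FGO column, Id3, an inhibitor of basic helix-loop-helix factors, was at 17.03 FPKM in WT and 101 in KO. Zfp707, a zinc finger gene, was at 6.55 and 61.5, and Ddx47, an RNA helicase, at 9.70 and 73.0. Snapc2, of the complex that activates snRNA genes, was at 1.101 and 14.2. Ctf1, a cytokine gene, was at 0.695 and 13.0. Tuft1 (1.93 and 15.8), Chmp6 of the ESCRT-III machinery (0.174 and 5.64) and Slc24a5 (0.0157 and 10.2) were also higher in KO. Rps27 was at 1.07 and 36.0 FPKM. Clec2f was listed at 0 in WT and 71.9 in KO, so no fold is given.

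Fewer genes were lower in KO at FGO. Gli3, a transcription factor of hedgehog signalling, was at 13.9 FPKM in WT and 5.30 in KO. Atp5k, a subunit of ATP synthase, was at 93.9 and 35.6. Gnrh1 was at 6.29 and 1.87, Lgi2 at 6.82 and 2.79, and Smim4 at 6.53 and 1.94. Rnaset2a was at 12.1 and 5.44. Rpl7a (21.7 and 0.815) and Eif3j1 (10.2 and 0.0980) stood furthest apart. Each of these was also at least 2-fold lower after rescaling.

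Some members of the fixed lists were also higher in KO at FGO. Ddx4, the germ cell helicase VASA, was at 15.4 FPKM in WT and 80.1 in KO. Kdm1b was at 11.04 and 54.0, and Tbpl2, the oocyte paralogue of TATA-binding protein, at 9.18 and 39.5. Patl2, a translational repressor of the oocyte, was at 24.0 and 126, and Ythdf2, which binds methylated RNA and promotes its decay, at 23.1 and 89.4. Wee1, an inhibitor of Cdk1, was at 4.59 and 22.3. Tfam, which packages mitochondrial DNA, was at 8.27 and 28.3. These 7 were also at least 0.8 above the median gene after rescaling. Of the 22 oocyte transcription factors and secreted proteins, 10 were at least 2-fold higher as deposited and 1 after rescaling. Of the 33 maternal effect genes, the numbers were again 10 and 1.

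As deposited, the oxidative phosphorylation and ribosomal protein lists had positive medians at FGO, 0.22 and 0.38. After rescaling these became -0.50 and -0.40, each below all 10000 random lists. Of the oxidative phosphorylation genes 64 of 75 lay below the median gene, and of the ribosomal protein genes 71 of 79. Cox7c was at 69.4 FPKM in WT and 40.5 in KO, Ndufs5 at 24.3 and 12.8 and Rpl30 at 9.11 and 4.02. Uqcrc1, of complex III, went the other way, at 8.94 and 46.0. The 45 RNA polymerase II and elongation genes had medians of 0.52 as deposited and -0.18 after rescaling (percentile 0.605). Against lists matched on transcript length as well this lay at percentile 1.86. Double-strand break repair had a rescaled median of 0.14 at FGO, at percentile 95.45 and, with length matched, 98.3. Polr2k was at 19.3 and 13.4 FPKM and Polr2l at 8.59 and 6.27. The 14 DNA methylation genes had 0.47 and -0.28 (percentile 1.64), with Dppa3, which guards oocyte methylation, at 105 and 85.8 and Dnmt1 at 311 and 405. The histone list had 0.39 and -0.30 (percentile 0.30, not matched on transcript length), with H4c8 at 6.72 and 6.18 FPKM. Beyond percentile 2.5 at either end lay 5 of the 20 lists at NGO, 6 at GO and 5 at FGO. About 1 would be there if genes varied independently. Genes of a list vary together, so these counts are no test against chance.

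**Figure D3:**
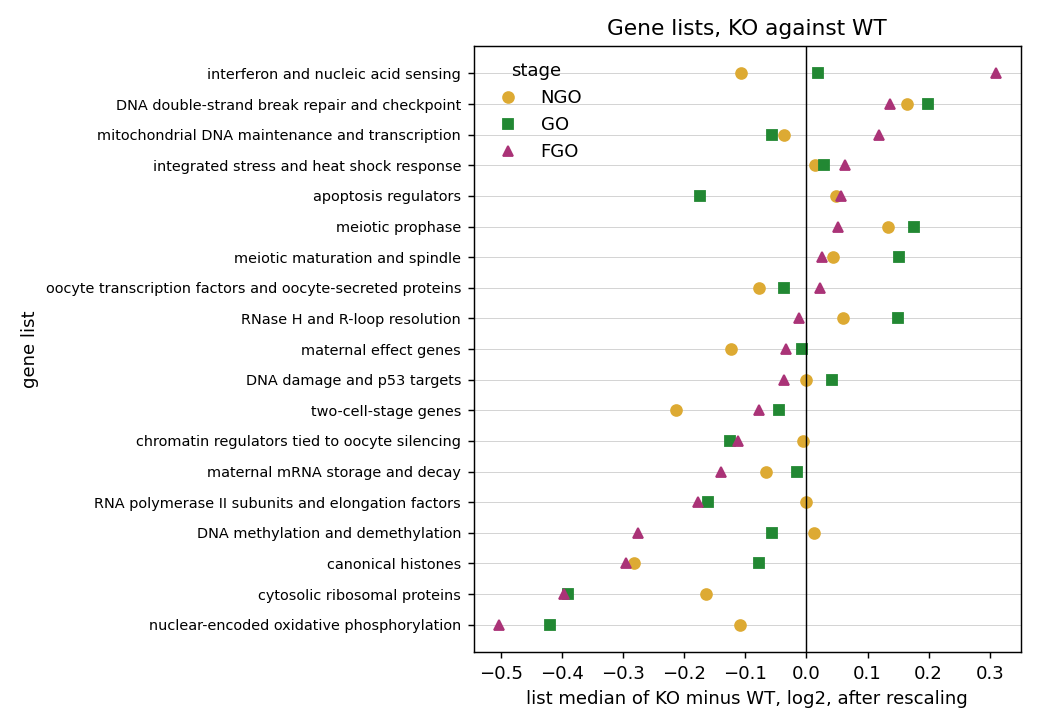
Median KO minus WT difference per gene list in log2 units after rescaling, for NGO (circles), GO (squares) and FGO (triangles). Oxidative phosphorylation stands at -0.42 at GO and -0.50 at FGO and ribosomal proteins at -0.39 and -0.40, while double-strand break repair stands at 0.16, 0.20 and 0.14 over the 3 stages.

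The remaining lists lay inside percentile 2.5 at either end at each stage of the KO to WT comparison. As deposited, each of their medians at FGO was above 0. Their rescaled medians at NGO, GO and FGO were 0.00, 0.04 and -0.04 for the 27 DNA damage and p53 targets and 0.05, -0.17 and 0.06 for the 22 apoptosis regulators. They were -0.01, -0.12 and -0.11 for the 46 chromatin regulators tied to silencing. Kmt2b, the H3K4 methyltransferase of oocytes, was at 5.76 FPKM in WT FGO and 4.71 in KO FGO, and Suz12 at 165 and 155. The 51 genes of maternal mRNA storage and decay had -0.07, -0.02 and -0.14, with Ybx2 at 90.7 and 91.5 FPKM in FGO. The 32 genes of mitochondrial DNA maintenance had -0.04, -0.06 and 0.12. The 28 stress response genes had 0.01, 0.03 and 0.06, with Hsph1 at 53.8 and 166 FPKM in FGO and Asns at 1.28 and 5.84. The 10 interferon and nucleic acid sensing genes had -0.11, 0.02 and 0.31, with Mavs at 5.17 and 16.1 FPKM in FGO and Irf3 at 4.17 and 12.2. The 7 genes of the two-cell stage had -0.21, -0.05 and -0.08. The oocyte transcription factor list had -0.08, -0.04 and 0.02 and the maternal effect list -0.12, -0.01 and -0.03.

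Markers of other ovarian cells were mostly under 1 FPKM. Of 24 granulosa cell markers, 5 were at 1 FPKM or more in the WT FGO column and 10 in the KO FGO column. Inha was at 1.17 FPKM in WT FGO and 9.32 in KO FGO, Gja1 at 0.965 and 6.96, Hsd17b1 at 0.845 and 3.71 and Kitl at 1.59 and 3.19. Of 4 markers picked after their values were seen, Hsd17b1 and Kitl are given above, and Amh and Foxl2, both strong granulosa genes, stood at 0.0206 and 0.0130 FPKM in WT FGO and at 0.282 and 0 in KO FGO. Esr2 was at 21.3 and 37.3 and Cyp19a1 at 6.16 and 10.4 FPKM. The rescaled median of the 7 granulosa markers with a mean of at least 1 was 0.07 at NGO, -0.15 at GO and 0.15 at FGO. Gene by gene, the median of their shift was -0.66 from NGO to GO (percentile 0.04) and 0.73 from GO to FGO (percentile 99.96). Inha, Gja1 and Kitl had their highest values in KO FGO, a column that counts towards the mean used to keep genes. The filter itself thus favours a rise to KO FGO, and no conclusion is drawn from the second percentile. At most 2 of 20 theca and stroma markers, 3 of 15 immune markers and 2 of 13 endothelial and blood markers reached 1 FPKM in any column. Among these C1qb stood at 46.8 FPKM in WT FGO and 70.5 in KO FGO, with C1qa at 0.322 and 0 and C1qc at 0 in both, Pecam1 at 8.46 and 14.6, and Dcn at 4.13 and 1.15.

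Over the 3 stages together, among genes that kept one direction after rescaling, Kdm1b had an averaged log2 difference of 1.26 as deposited and 1.08 after rescaling. Xbp1, a factor of the unfolded protein response, had 1.18 and 1.004, and Maged1 1.20 and 1.02. Myot (1.16 and 0.98), Kctd3 (1.12 and 0.95), Snapc2 (1.19 and 0.98), Zfp707 (1.15 and 0.96), Zfp97 (1.18 and 1.003), Llgl1 (1.16 and 0.99) and Oog1 (1.93 and 2.02) completed the 10 largest. On the lower side were Rnaseh1 (-2.29 and -2.52), Ndufs5-ps (-2.49 and -2.58), Rnaset2a (-1.48 and -1.65), Gli3 (-1.06 and -1.30) and Tcstv1 (-1.01 and -1.24). Insm1 (-1.01 and -1.13), Cphx2 (-0.99 and -1.33), Smim4 (listed at 0 in KO GO), Lsm5 (-0.90 and -1.08) and Emx2 (-0.81 and -1.05) followed. In all, 56 genes were higher and 10 lower on average, and 12 and 18 after rescaling. The averaged rescaled list medians were -0.37 for oxidative phosphorylation, -0.28 for ribosomal proteins, -0.21 for histones, -0.13 for RNA polymerase II (0.02 as deposited) and 0.14 for double-strand break repair.

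Genes past 2-fold were partly shared between GO and FGO. After rescaling, 34 of the 129 genes lower at GO were also among the 95 lower at FGO, against 1.21 for independent lists. Named after their values were seen, they included Cox7c, Cox6b1, Uqcrh, Cox17, Rps15, Snrpe, Gli3 and Insm1. Of the 106 genes higher at GO, 14 were among the 170 higher at FGO, against 1.78. These included Kdm1b, Ect2, Ddi2, Xbp1, Hadh, Maged1 and Myot. Between NGO and GO, 9 lower genes were shared against 0.459. Across all genes the rescaled differences at GO and FGO had a Pearson r of 0.54 and a Spearman rho of 0.59. NGO and GO had 0.444 and 0.469, and NGO and FGO 0.279 and 0.319. Genes are not independent replicates, and these stage comparisons share no column.

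From NGO to GO most genes were higher in GO, in both genotypes. In WT, Upp1, which breaks down uridine, was at 7.74 FPKM in NGO and 222 in GO. Ehf, an ETS factor gene, was at 0.820 and 42.5, Mbd3l2 at 0.188 and 29.4, Cphx3 at 0.0637 and 32.8 and Oog1 at 0.0670 and 148. The NLR-family genes Nlrp9b (24.4 and 285) and Nlrp9c (10.8 and 188) and the secreted-protein gene Oosp3 (27.0 and 201) were also higher in GO. Sohlh1 and Sohlh2, transcription factors of early oocytes, were at 6.37 and 2.51 and at 9.24 and 3.87 FPKM. Maged1 (32.2 and 9.61), Marcksl1 (18.1 and 4.88) and Gipc1 (15.5 and 7.85) were lower in GO too, Gipc1 by just under 2-fold on this scale. In WT 5540 genes were higher and 13 lower, and in KO 5822 and 9. After rescaling the splits were 613 and 331 in WT and 543 and 262 in KO.

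The two-cell-stage list, with 7 of 29 genes compared, had a rescaled WT median of 0.88 from NGO to GO (percentile 99.97). Tcstv3 was at 1.58 and 50.1 FPKM. A member low at NGO passes the filter on the mean through its later columns, which can favour a rise. No conclusion is drawn from this percentile. The chromatin regulator list had 0.17 (percentile 97.71), with Setdb2 at 4.12 and 21.1 and Hells at 8.60 and 40.8. The stress list (-0.31), the ribosomal proteins (-0.24) and oxidative phosphorylation (-0.19) lay below percentile 2.5, although their medians as deposited were 0.91, 1.01 and 1.09. In KO the ribosomal protein and oxidative phosphorylation medians over this step were -0.52 and -0.53 after rescaling, and 0.82 and 0.87 as deposited. Random lists for this step were matched on expression only. Across genes the rescaled step had a Spearman rho with transcript length of 0.12 in WT and 0.10 in KO. With GC content rho was -0.28 in WT and -0.26 in KO. In WT the granulosa marker list had 0.85, from Esr2 at 0.744 and 8.28 FPKM and other genes with low values.

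From GO to FGO the WT column was lower for many genes and higher for others. Id3 was at 195 FPKM in GO and 17.03 in FGO, Zfp707 at 89.2 and 6.55, Ier2, an immediate early gene, at 21.8 and 1.0503, and Ifi47 at 11.4 and 0.0391. Clec2f was at 12.8 FPKM in GO and listed at 0 in FGO. Among list members, Zfp36l2, which promotes decay of AU-rich mRNA, was at 16.0 and 1.91, Patl2 at 125 and 24.0, Ddx4 at 72.8 and 15.4, Tbpl2 at 37.8 and 9.18 and Uqcrc1 at 51.6 and 8.94. In the other direction Rgn, a calcium-binding protein, was at 5.47 and 108, Dnajc5b at 2.40 and 36.7, Tuba3b at 1.76 and 33.8 and Prr32 at 0.273 and 15.3. Rn45s was listed at 0 in GO and 4820 in FGO. Aurka, a spindle kinase, was at 140 and 295 FPKM and Ccnb3, a meiotic cyclin, at 6.66 and 19.8. In WT 657 genes were higher and 932 lower in FGO, and 584 and 842 after rescaling.

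The meiotic maturation list had a rescaled WT median of 0.46 from GO to FGO (percentile 99.99) and the histone list 0.71 (percentile 99.97). Oxidative phosphorylation had 0.32 (percentile 99.27). Random lists for this step too were matched on expression only. Across genes the rescaled step had a Spearman rho with transcript length of -0.14 in WT and -0.20 in KO. With GC content rho was -0.23 in WT and -0.25 in KO. In WT the oocyte transcription factor list had -0.09 (percentile 0.29) and the maternal effect list -0.05 (percentile 0.08). Of their members, 10 and 15 lay above the median gene and 12 and 18 below it. Their low percentiles thus mean that random lists of like expression lay higher, more than that these lists fell. The stress list had -0.22 (percentile 0.33), with Hsp90ab1 at 341 FPKM in GO and 151 in FGO. The DNA damage list had -0.31 (percentile 1.34), with Aen at 7.41 and 2.84. In KO, 3946 genes were higher and 52 lower in FGO than in GO as deposited. After rescaling the KO split was 649 and 370, and with equal column totals it turned to 556 and 639. The KO list medians over this step after rescaling were 0.51 for histones (percentile 99.73), 0.29 for ribosomal proteins (99.86) and 1.003 for granulosa markers (99.6). The granulosa value rests on 7 of 24 markers and ends in KO FGO, towards which the filter on the mean favours a rise. No conclusion is drawn from its percentile. Stress (-0.30, percentile 0.03), maternal effect (-0.07, 0.16), DNA damage (-0.32, 0.38), oocyte transcription factor (-0.07, 0.74) and maternal mRNA storage genes (-0.10, 0.93) lay below percentile 2.5 after rescaling. Each of these medians was above 0 as deposited. Meiotic maturation (0.27, 97.26) and oxidative phosphorylation (0.15, 68.8) lay inside percentile 2.5 at either end.

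After rescaling, the KO step resembled the WT step gene by gene in direction and was smaller for genes with lower values in FGO. As deposited the directions differed, with 3946 genes higher and 52 lower in KO FGO against 657 and 932 in WT FGO. The 5 genes named next were given above for their fall in WT, a choice that by itself favours a smaller fall in KO. Id3 was at 184 FPKM in KO GO and 101 in KO FGO, Zfp707 at 109 and 61.5, Ddx4 at 123 and 80.1, Ier2 at 21.2 and 6.88 and Ifi47 at 8.02 and 2.95. Across all genes the steps from GO to FGO in WT and KO had a Pearson r of 0.81 and a Spearman rho of 0.83. From NGO to GO these were 0.76 and 0.72. The orthogonal slope of the KO step on the WT step after rescaling was 0.840 for GO to FGO and 0.955 for NGO to GO. The 842 genes chosen for a 2-fold lower rescaled value in WT FGO had medians of -1.35 in WT and -0.83 in KO. The 370 genes chosen for the same in KO had medians of -1.18 in KO and -1.40 in WT. As deposited, the 932 genes so chosen in WT had medians of -1.38 in WT and -0.15 in KO. The 52 so chosen in KO had -1.17 in KO and -1.86 in WT. Of the 842 genes, 122 were among the 170 that were higher in KO FGO than in WT FGO after rescaling, against 14.2 for independent lists. Both of these lists use the WT FGO column, so part of the overlap comes from that column alone.

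**Figure D4:**
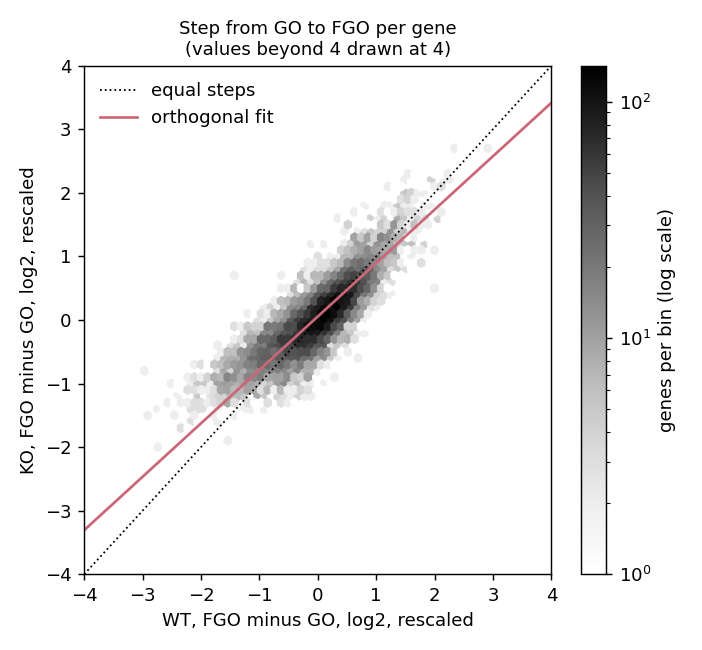
Difference between FGO and GO per gene in log2 units after rescaling, WT on the x axis and KO on the y axis, with shading for the number of genes per bin on a log scale, a dotted line of equal steps and the orthogonal fit. The fit has a slope of 0.840, and the 842 genes at least 2-fold lower in WT FGO have medians of -1.35 in WT and -0.83 in KO.

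The KO to WT difference itself differed most between stages for a few genes. Clec2f and Rn45s rank first, but rest on WT entries at 0, so no size is given for them here. From GO to FGO the rescaled difference moved by 3.66 for Rps27, 3.42 for Amd1 and -3.996 for Eif3j1. From NGO to GO it moved by -3.67 for Oog1, -2.93 for Amd1, -2.72 for Smim27 and 3.54 for Tgoln2. From NGO to FGO it moved by -5.55 for Eif3j1, -3.83 for Rpl7a, 3.34 for Ctf1 and 3.34 for Rps27, again behind Clec2f. Entries under 0.1 FPKM take part in the shifts of Amd1, Eif3j1, Oog1, Tgoln2 and Rps27. As lists, the oocyte transcription factors had a median shift of 0.18 from GO to FGO (percentile 99.94), and Tbpl2, Sohlh2 and Taf4b stood at 39.5, 11.2 and 8.86 FPKM in KO FGO. Oxidative phosphorylation shifted by -0.24 from NGO to GO and ribosomal proteins by -0.26, both below all 10000 random lists, and histones by 0.33 (percentile 99.92). Random lists for these shifts were not matched on transcript length. All 632 genes with transcripts of up to 1000 nt had rescaled medians of -0.23 at NGO and -0.40 at GO. Transcript length may thus account for part of the first 2 shifts, which was not tested. From GO to FGO the lists of RNase H and R-loop resolution (-0.12), maternal mRNA storage (-0.12), meiotic maturation (-0.13) and oxidative phosphorylation (-0.11) lay below percentile 2.5 after rescaling, although each median was above 0 as deposited. Shifts of at least 2-fold from GO to FGO numbered 2933 up and 15 down as deposited, and 196 and 49 after rescaling.

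Several of the named genes share sequence or position with others. Of the 75 genes named by the fixed rule apart from list members, 11 of the 71 searched had at least 50% of their longest transcript matched at 95% identity in another gene. A further check found 24 of the 75 overlapping another gene. Oog1 matched Gm10436, Cphx2 matched Cphx3, Rnaset2a matched Rnaset2b, Amd1 matched Amd2, Phgdh matched Gm9252, Zfp97 matched Zfp960 and Rpl7a matched a transcript of Ciapin1 over 81.7% of its length. Ndufs5-ps overlaps Zbtb20, Llgl1 overlaps Flii, Ddi2 overlaps Rsc1a1, Kdm1b overlaps Dek, Slc24a5 overlaps Myef2, Tmem243 overlaps Dmtf1 and Fbxw5 overlaps C8g. Tcstv1 matched Gm21818 over 58.5% and Tuba3b matched Tuba3a over 81.5%. Of the list members, Tcstv3 matched Gm21761 over 65.1%, Polr2k matched Gm46136 over 55.9% and Dppa3 matched Dppa3-ps over 54.1%. Values of these genes are uncertain, since the authors' quantification could split reads between copies or between neighbours in unstranded data. Rps27 matched Rps27rt over 38.4% and Eif3j1 matched Eif3j2 over 43.8%, so that they are uncertain as well.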

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

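Of the tests in this part, those of the scale factor, of the kept transcripts, of the FGO mixture without a scale factor, of the nearest genes in length and of transcript length at GO were chosen only after the result was seen. The other tests on matched gene lists were written with the list medians known and the matched percentiles unknown, and the other FGO mixture test with an overlap of related gene sets known and the share outside the range unknown.

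The ratio of total FPKM, KO over WT, stands out because it was below 1 at NGO and GO and 1.58 at FGO, a difference between groups that has no replicate check. Several genes stand out because their rescaled KO to WT difference was at least 2-fold in opposite directions at 2 stages. Clec2f was lower in KO at GO and higher at FGO, 7.11 apart on the log2 scale, and Ddx47 likewise, 3.15 apart. Ctf1 was lower in KO at NGO and higher at FGO, 3.34 apart. Eif3j1 was higher in KO at NGO and lower at FGO, 5.55 apart. Tgoln2 was lower at NGO and higher at GO, 3.54 apart. Rn45s was higher at GO and lower at FGO, 12.4 apart, with WT entries at 0 in NGO and GO. The difference between stages was not tested for any of these, and entries at or near 0 take part in those of Clec2f, Eif3j1, Rn45s and Tgoln2, so the pseudocount sets much of their size.

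For the excess of most genes in the KO FGO column, a single scale factor could come from the spike-in adjustment. The table holds 0 spike-in lines, so one scale factor as the cause of the median difference could not be tested and stays open. One factor as the whole cause of the FGO differences is excluded, since the rescaled differences at FGO and at GO, which share no column, had a Spearman rho of 0.594 across genes (error 0.00755 over resampled genes, which leaves out variation between samples). KO oocytes may also keep transcripts that WT oocytes lose between GO and FGO. Genes chosen for their fall in KO had a WT to KO ratio of rescaled steps of 1.18, as that would need. The criterion was set after similar values were known, and noise in the WT FGO column could give the same. Rescaling divides out the median excess, so this ratio does not bear on it. As deposited, 2035 of the 2628 genes 2-fold apart at FGO lay above the range of WT GO and WT FGO. Keeping the WT GO level alone, without a scale factor, would not give these values. A mixture of WT GO and WT FGO oocytes without a scale factor is excluded as the cause, as 0.778 of the 2-fold genes lay outside the WT range as deposited, while with a scale factor as well a mixture stays open, at 0.419 after rescaling.

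For the low oxidative phosphorylation and ribosomal protein genes at GO and FGO, short transcripts could be the cause, because Smart-seq2 yield may depend on transcript length. With transcript length matched, in bins or among the 50 genes nearest in length, the highest oxidative phosphorylation percentile at GO and FGO was 0.43. The list thus lay lower than nearly all lists of like length. Lists of nearest length had medians of -0.29 at GO and -0.24 at FGO against -0.42 and -0.50, so that length may account for part. Length was that of the longest transcript and the percentile is no p-value, so length as the sole cause is not excluded. For ribosomal proteins the highest percentile was 4.29, from GO in bins. Among the nearest genes it was 3.22 at GO with both lists in the pool and 1.33 with them left out. Transcript length may thus suffice at GO, but this depends on the match. At FGO alone the percentile was 0.035 in bins and 0.105 with the nearest genes. At NGO the oxidative phosphorylation list turned from percentile 2.13 to 98.3 with length matched in bins. Among the nearest genes it was at 76.4 with both lists in the pool and 77.7 with them left out. Its median at NGO was thus no lower than that of genes of like length. With transcript GC content matched, the highest percentile at GO and FGO was 0 for oxidative phosphorylation and 0 for ribosomal proteins. GC content as matched thus did not account for the low medians there.

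At GO the KO to WT difference ran against the WT difference between FGO and NGO, with a Pearson r of -0.29 across genes. KO GO oocytes might include less grown ones, as a mixture of WT NGO and WT GO oocytes. Of the genes 2-fold apart, 0.382 lay outside the range of those columns as deposited and 0.604 after rescaling, so the mixture is undecided. Among genes with a known length, r was -0.34 before and -0.33 after the length trend was removed. Length of the longest transcript thus accounted for little of it.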

How the results depend on the processing

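No paired analysis was possible because the table has 1 column per genotype and stage. For the same reason the moderated linear models, leave-one-out, the replicate block, the fit within each group, the intensity trend, camera and fry and the permutations were not run. Of the main values under the alternatives 77 stayed within the limits set and 24 moved. With a pseudocount of 0.1 the 2-fold genes were 272 in place of 36 at NGO (48 higher, 224 lower), 670 in place of 301 at GO, 264 in place of 66 averaged and 615 in place of 208 for the shift from NGO to GO, because a smaller pseudocount widens differences of low values by construction. With equal totals they were 64 at NGO, 321 at FGO (2628 as deposited), 35 averaged, 1033 for WT NGO to GO (5553), 906 in KO (5831), 1195 for KO GO to FGO (3998), 333 for the shift from GO to FGO (2948) and 402 from NGO to FGO (3704). With the median ratio these were 265 at FGO, 30 averaged, 944, 805, 1019, 245 and 333. The split of higher and lower calls turned in 4 cases: with equal totals at GO, from 96 and 205 to 156 and 134, and for KO GO to FGO, to 556 and 639, with the median ratio for the average, to 12 and 18, and with a mean of at least 5 for the shift from NGO to GO, from 101 and 107 to 75 and 60. Removing a common factor shifts all genes by construction. With a mean of at least 5 there were 789 for WT GO to FGO (1589), 135 and 1946 for the shifts from NGO to GO and from GO to FGO, since fewer genes are compared. Without a filter r of the steps was 0.88 for NGO to GO and 0.67 for GO to FGO; the cause was not tested. Depth is unknown and limits low values.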

Other observations

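The short-lived mRNA test in this part was chosen only after the result was seen.

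Id3, Ier2 and other genes whose mRNA turns over fast stood out among those lower in WT FGO than in WT GO. A list of 27 immediate early and other short-lived mRNAs was written to ask whether they as a group may be kept in KO FGO. In WT the list had a rescaled median of -0.83 from GO to FGO and in KO -0.66. At FGO its rescaled KO to WT median was 0.22 with all members, at percentile 96.5, and 0.10 without the 7 members seen before, at percentile 65.3. With all members 4 were at least 2-fold higher in KO FGO after rescaling, and without those 7 there were 0. Leaving out members with known values excludes nothing, so whether short-lived mRNAs as a group are kept in KO FGO stays open.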
